A study of Arabidopsis thaliana with 17 samples.

How the data were processed

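Seeds of the Ws-0 accession were taken, per the labels' protocols, from siliques of 1.1 to 1.4 cm on plants of 38 to 46 days grown in continuous light, with embryos of 24 to 32 µm at the globular stage. Tissue was fixed in ethanol and acetic acid, embedded in paraffin and sectioned at 5 or 7 µm, and compartments were captured by laser on a Leica LMD6000, per the labels' protocols. Total RNA was extracted with a column kit and treated with DNase, 2 to 4 ng were amplified with the NuGEN WT-Ovation Pico system, and biotin-labelled product was hybridised to ATH1 arrays, per the labels' protocols.

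The values are intensities on a linear scale, 1 per probe set and array, deposited by the authors as 1 table of 17 arrays. GCOS, the Affymetrix software, is named per the submitters' processing notes; its version, its algorithm and its detection calls are not given in the sources used here. From the values, each array was scaled as a whole, since the mean without the highest and lowest 2% lay between 500.042 and 500.072 on every array. Array medians ran from 97.3 to 179. Signal that favours 3' ends can lower probe sets that lie far from them. Whether amplification or the state of the RNA favoured 3' ends here was not tested.

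The values were used as scaled. Of 22810 probe sets, 64 controls were left out and 22746 tested, on log2(intensity + 31), where 31 is the median over arrays of the array medians divided by 4 and rounded, so log2 differences understate the change of dim genes. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 17 arrays, with 9 residual degrees of freedom, eBayes with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over all probe sets, and a threshold of 0.05. The 8 comparisons were embryo proper with suspensor, chalazal with other endosperm, micropylar with peripheral endosperm, chalazal with general seed coat, the 3 pairs of regions, and whole seed with the mean of the 7 compartments. Regions were means of their compartments. A difference of differences compared the chalazal step of endosperm with that of seed coat. A gene was called highest in a compartment where the largest of 6 one-sided p-values, against each other compartment, passed after adjustment.

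For background, the limit of an array was its highest value among 27 control probe sets of bacterial genes that are not spiked in, from 49.2 to 144 between arrays, a choice made after the data were seen. Where an array of the dimmer group was not above its limit, the fold was computed with that array at the higher of its limit and its value, and written as "at least". Folds are ratios of the geometric mean intensities of the groups, averaged over groups where a side held several.

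Gene names came from a table of probe annotation. Of the probe sets tested, 13513 name 1 gene, of which 13436 matched a current name of the TAIR10.1 annotation, 503 name several and 8730 are unnamed here and were tested without a name. Genes named in the text were those with the 8 largest log2 differences per direction and comparison, among called probe sets whose samples did not overlap between sides, with the brighter side above the median of all probe sets and with 1 gene. The 5 genes with the largest lead per compartment and members of the lists, as examples, were added. The 21 gene lists, the named gene rule, the tests and most of the alternatives were fixed before the data were examined.

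Of the 21 lists, 8 had at least 3 measured genes and were tested with camera at a preset correlation of 0.01, adjusted over 72 tests, with an estimated correlation and with fry beside it. Measured were 4 of 30 embryo proper markers, 4 of 21 endosperm markers, 10 of 15 type I MADS-box genes and 5 of 26 transporters. For photosynthesis, cell cycle, cytokinin and pollen genes it was 10 of 40, 3 of 32, 3 of 24 and 4 of 10. The rest had no probe set that names them alone here, so a list result holds for its measured genes only. Another 6 lists had 1 or 2 measured genes, and 7 had none named here. The pipeline was tested on simulated data with the real spread. For embryo proper with suspensor it called 0%, 28%, 66% and 86% of 50 probe sets changed by 1, 2, 3 and 4 on the log2 scale, with 5 false among 95 calls. For genes highest in chalazal endosperm it called 0%, 24%, 54% and 84%, and for micropylar endosperm 0%, 18%, 54% and 72%, with 0 false among 81 and 72 calls. Of 20 lists of 10 probe sets shifted by 1.5 it found 20, and of 20 unshifted lists 0. Most of the lists tested were smaller, with 3 to 5 measured genes, so this recovery does not carry over to them. The simulated probe sets varied independently and these p-values were not adjusted. That result therefore says nothing on lists of genes that vary together, as genes of the real lists can.

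Alternatives were no offset, an offset 4 times as large, quantile normalization, log2 values shifted to a common 75th percentile, a filter on dim probe sets, no intensity trend, array weights, the replicate number as a block, only the groups compared, the 2 regions of a comparison as groups in a fit of their arrays alone, and each array left out in turn. Chosen after seeing the data were a fit of only probe sets that name 1 gene, the level of 18 hybridisation controls as a covariate, a fit without the 2 arrays of highest control signal, intensities scaled to a common 75th percentile before the offset, and the regions and whole seed as 4 groups over all arrays. No 2 arrays held identical values.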

Results

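RNA was measured on Affymetrix ATH1 arrays, which carry 22810 probe sets for Arabidopsis thaliana, in 7 laser-captured compartments of seeds holding a globular embryo and in whole seeds of the same stage. The embryo gave the embryo proper and the suspensor, the file of cells that joins the embryo to the mother tissue. The endosperm, which feeds the embryo, gave a micropylar part around the embryo, a peripheral part and a chalazal part at the opposite pole. The seed coat, a tissue of the mother plant, gave a chalazal part and a general part. Each group had 2 arrays, named biological replicates by the labels, and chalazal endosperm had 3, which made 17 arrays in 8 groups. The labels do not tie captures to seeds or plants, so p-values measure only the spread between these samples and may be too small where captures of a group shared plants.

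The question was how gene activity is divided among the parts of a young seed. Levels are mean array intensities ± SD over the arrays of a group, and differences are on the log2 scale ± SE. A gene not above background on every array of the lower group has only a bound, written as "at least". Folds are ratios of geometric means, over the arrays of a group and then over the groups of a side, so they can lie above the ratio of the levels printed, which are arithmetic means. Between 44.5% and 66.0% of the probe sets of an array lay above its background limit, and the small number of arrays per group limits the precision. Across probe sets, which are not independent replicates, arrays of a group correlated at r = 0.864 to 0.939 and arrays of different groups at 0.529 to 0.872. Chalazal endosperm stood farthest from the other groups, with mean r between 0.564 and 0.676, while whole seed lay closest to general seed coat at 0.869. The ratio of 3' to 5' signal of the control gene GAPDH, a sign of how complete the amplified RNA was, was 27.7, 16.1 and 10.8 on the 3 chalazal endosperm arrays, and 16.8 ± 8.34 in micropylar endosperm and 12.4 ± 5.74 in embryo proper (SD, n = 2). It was 9.77 ± 4.81 in peripheral endosperm, 6.27 ± 1.17 in suspensor, 6.20 ± 2.17 in chalazal seed coat, 5.30 ± 0.803 in general seed coat and 2.99 ± 0.145 in whole seed.

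**Figure D1:**
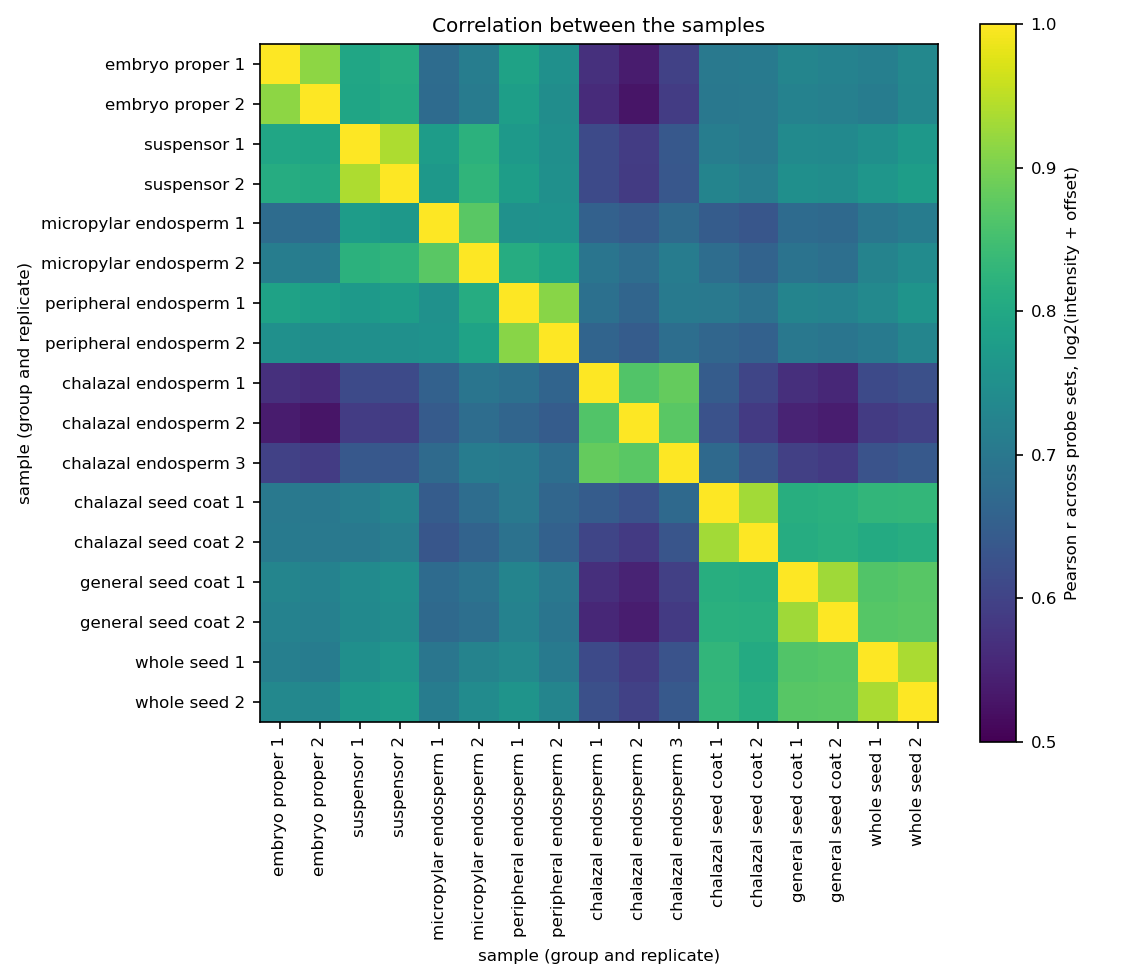
Pearson correlation across probe sets between the 17 samples, on log2(intensity + offset), with samples named by group and replicate on both axes and colour giving r from 0.5 to 1. Samples of a group lie between 0.864 and 0.939, and the 3 chalazal endosperm samples stand apart from the rest.

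Embryo proper and suspensor are both parts of the embryo, and their comparison asked which transcripts set them apart. AUR1 and AUR2, Aurora kinases that act at mitosis, were higher in the embryo proper, with AUR2 at 2493 ± 213 against 137 ± 88.2 in suspensor (SD, n = 2; at least 19.2-fold higher, with 1 of 2 suspensor arrays above background). AT3G15720 reached 7267 ± 1186 in the embryo proper (at least 101-fold above suspensor, 1 of 2 arrays above background, adjusted p = 1.5e-06), and scpl25, a serine carboxypeptidase-like gene, reached 4763 ± 82.5 (at least 66.3-fold, 1 of 2 arrays above background). ROXY1, a glutaredoxin known from petal development, stood at 2156 ± 307 and was at least 30.8-fold higher. In suspensor, AT2G28680 stood at 39987 ± 8579, 230.0-fold above the embryo proper, and PAP20, named as a purple acid phosphatase, stood at 11126 ± 687, at least 91.0-fold higher (adjusted p = 1.4e-09). AT1G62290 followed at 8607 ± 681 (at least 70.3-fold). SWEET9, a sugar transporter of nectaries, measured 1623 ± 919 in suspensor and 372 ± 12.1 in the embryo proper, a log2 difference of -1.92 ± 0.68 with adjusted p = 0.0618.

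Of the 22746 probe sets tested, 1287 were higher in the embryo proper and 1693 in suspensor, 2980 in all. The GAPDH ratio was 12.4 ± 5.74 in embryo proper and 6.27 ± 1.17 in suspensor (SD, n = 2), and the part of RNA quality in this count was not tested. Only 3 of the 32 cell cycle genes listed were measured. Of these, 2 were higher, none lower and 1, MCM7, not called (2 adjusted over the list alone, median log2 difference 3.08, camera adjusted p = 0.00250). The other 5 of the 8 genes named for the embryo proper, AT2G41890, AT1G80450, AT5G40460, AT1G53860 and AT3G15680, were at least 23.3-fold to at least 41.7-fold higher. The other 5 named for suspensor, AT3G59480, AT1G20500, AT3G54940, AT1G51850 and AT4G23080, were at least 19.8-fold to at least 38.9-fold higher. The count rested on every library of both groups: it was 1897 and 1748 without embryo proper 1 and 2, and 1578 and 1615 without suspensor 1 and 2. Among 124 bright genes called higher in micropylar endosperm than in the other endosperm and seed coat compartments, the suspensor level was a median 28.6% of the micropylar level. AT4G23080 was also at 14281 ± 5659.5 in micropylar endosperm.

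Micropylar endosperm, the part around the embryo, was compared with peripheral endosperm. EXPA21, an expansin, a class of proteins that loosen cell walls, stood at 72446 ± 15571 against 311 ± 139 (SD, n = 2; 243-fold, adjusted p = 4.4e-12). TBL15, of a family that acetylates wall polymers, stood at 26851 ± 1129.5, at least 374-fold above peripheral endosperm with 1 of 2 arrays above background there, and AT4G20800 stood at 38878 ± 151 (364-fold). Suspensor held EXPA21 at 26421 ± 4304, TBL15 at 7014 ± 419 and AT4G20800 at 9469 ± 1930.5. IKU2, a receptor kinase needed for endosperm growth, measured 849 ± 182 in micropylar and 39.3 ± 53.2 in peripheral endosperm (log2 difference 3.88 ± 0.65, adjusted p = 1.3e-04). Of the 4 endosperm markers, 3 were lower in micropylar endosperm, AGL40, AGL62 and MPC, and IKU2 was higher (3 and 1 adjusted over the list alone; median -2.08). The list test gave adjusted p = 0.125, and 0.0463 when only these 4 arrays were fitted. In peripheral endosperm, UGT87A2, a glycosyltransferase, stood at 5900.4 ± 2433 (at least 39.4-fold higher), and MPC, a gene expressed from the maternal allele in endosperm, at 5806 ± 354 (at least 28.0-fold, 1 of 2 micropylar arrays above background). Cpn60beta4, a plastid chaperonin subunit, stood at 1482 ± 482 (at least 10.1-fold) and FOLB1, an enzyme of folate synthesis, at 1595 ± 1227 (at least 9.35-fold).

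Genes of photosynthesis were higher in peripheral than in micropylar endosperm: of 10 measured, 5 were lower in micropylar endosperm, none higher and 5 not called (6 lower adjusted over the list alone; median -1.76, adjusted p = 1.1e-05). SBPASE, an enzyme of the Calvin cycle, went from 1762 ± 313 in micropylar to 16205 ± 1062 in peripheral endosperm, and PRK, another, from 3593 ± 1030.4 to 26881 ± 12901. Type I MADS-box genes, transcription factors many of which act in endosperm, had 5 of 10 lower in micropylar endosperm, none higher and 5 not called (6 lower adjusted over the list alone; median -1.74, adjusted p = 5.0e-04). Of the 3 cell cycle genes, 2 were lower and 1 not called (3 lower adjusted over the list alone; median -3.09, adjusted p = 0.00250), with AUR1 at 123 ± 16.7 in micropylar and 1373 ± 489 in peripheral endosperm. In all, 1466 probe sets were higher and 1579 lower in micropylar endosperm, 3045 together. The count was 1866 without micropylar endosperm 1, 1807 without peripheral endosperm 2, and 1480 when only these 4 arrays were fitted.

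Chalazal endosperm was compared with the mean of the other endosperm parts. AT3G03410 stood at 104929 ± 8728 (SD, n = 3) against 12.1 ± 11.3 in micropylar and 849.7 ± 912 in peripheral endosperm (SD, n = 2), and AT1G07690 at 85828 ± 23228 against 13.0 ± 8.80 and 499 ± 611. They were at least 372-fold and at least 426-fold above the geometric mean of the other endosperm, with 2 of 4 and 1 of 4 arrays there above background (adjusted p = 1.5e-13 and 1.6e-13). SBT4.13, a subtilisin-like protease, stood at 27655 ± 1886 (at least 191-fold, 1 of 4 arrays above background). Lower in chalazal endosperm were SBT5.4, another subtilase (25.8 ± 10.3 against 9359.7 ± 119 and 2442 ± 1088; at least 40.8-fold), GPDHp, a plastid glycerol-3-phosphate dehydrogenase (61.9-fold), and SAE1A, a subunit of the enzyme that activates SUMO (at least 21.8-fold).

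Type I MADS-box genes were higher in chalazal endosperm, with 6 of 10 higher, none lower and 4 not called (6 adjusted over the list alone; median 1.90, adjusted p = 2.7e-04). AGL33 stood at 11862 ± 1959.8 (at least 103-fold, 1 of 4 arrays of the other endosperm above background), AGL40 at 9434 ± 4039 and AGL35 at 4469 ± 1028, while AGL62, needed to keep endosperm from cellularising early, stood at 4863 ± 1071 against 861 ± 221 in micropylar and 2942 ± 997 in peripheral endosperm. The other endosperm is a mean of its parts, and peripheral endosperm came close for some genes. AGL28 stood at 2598 ± 900 in chalazal and 2127 ± 807 in peripheral endosperm, and AGL23 at 2097 ± 326 and 1172 ± 39.1. AGL33, AGL40 and AGL35 stood at 57.4 ± 68.6, 1509 ± 458 and 1056 ± 951 in peripheral endosperm. Photosynthesis genes went the other way, with 9 of 10 lower, none higher and 1 not called (9 adjusted over the list alone; median -1.90, adjusted p = 4.7e-06). PSAN, a subunit of photosystem I, stood at 199 ± 42.3 against 1003 ± 159 and 6260.1 ± 174, and PRK, not called, at 12446 ± 5418. Endosperm markers split, with AGL40 and AGL62 higher and IKU2 and MPC lower (2 and 2 adjusted over the list alone), and the list test was not passed. ARR19, a response regulator listed with cytokinin genes, stood at 6964 ± 1585 (at least 25.4-fold, 2 of 4 arrays above background), and SBE2.2, a starch branching enzyme, at 149.8 ± 80.7 against 1491 ± 61.6 and 1699.8 ± 295. In all, 2569 probe sets were higher and 3409 lower in chalazal endosperm, 5978 of 22746, so that 43.0% of calls were higher, against 54.4% with a common 75th percentile. A fit of these arrays alone, with the other endosperm as 1 group, called 2570 in place of 5978. The groups of highest GAPDH ratio, chalazal and micropylar endosperm, stand on opposite sides of this comparison.

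The chalazal part of the seed coat, where the vascular strand ends, was compared with the general part. SWEET10, a sugar exporter, stood at 6520.0 ± 783 in chalazal against 26.6 ± 29.1 in general seed coat (SD, n = 2; at least 80.3-fold, adjusted p = 5.6e-08), and SWEET4 at 1489 ± 408 against 11.1 ± 12.7 (at least 18.0-fold). AT3G10590 reached 47779.7 ± 9511 (at least 584-fold), AT4G22050 23570.5 ± 6013 (at least 286-fold) and AT1G12180 57248 ± 12535 (293-fold). In general seed coat, THI2.1, a thionin that acts against microbes, stood at 34448 ± 3991 against 339 ± 143 (106-fold, adjusted p = 1.5e-06), and scpl20 at 17606 ± 614 (110.1-fold). BAN, which makes the precursors of the tannins that colour the seed coat, measured 7867 ± 2119 in general and 2197 ± 160.2 in chalazal seed coat (log2 difference -1.80 ± 0.57, adjusted p = 0.0533).

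Of the 5 transporters measured, 2 were higher in chalazal seed coat, SWEET4 and SWEET10, and 3 were not called (2 adjusted over the list alone). The list's median was 0.07 and its mean 2.35, and its test gave adjusted p = 0.00483, against adjusted p = 0.213 with an estimated correlation. Of 10 photosynthesis genes, 3 were lower in chalazal seed coat, none higher and 7 not called (5 lower adjusted over the list alone; median -1.07, adjusted p = 0.00462), which became adjusted p = 0.144 with an estimated correlation and 0.0699 without general seed coat 1. In all, 783 probe sets were higher in chalazal and 804 in general seed coat, 1587 together. The count was 841 and 882 without chalazal seed coat 1 and 2, 883 and 787 without general seed coat 1 and 2, 835 without an offset and 2606 with array weights. Among 323 bright genes called higher in chalazal endosperm than in every compartment but chalazal seed coat, the chalazal seed coat level was a median 5.21% of the chalazal endosperm level, AT3G03410 being at 6462 ± 5681 there.

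**Figure D2:**
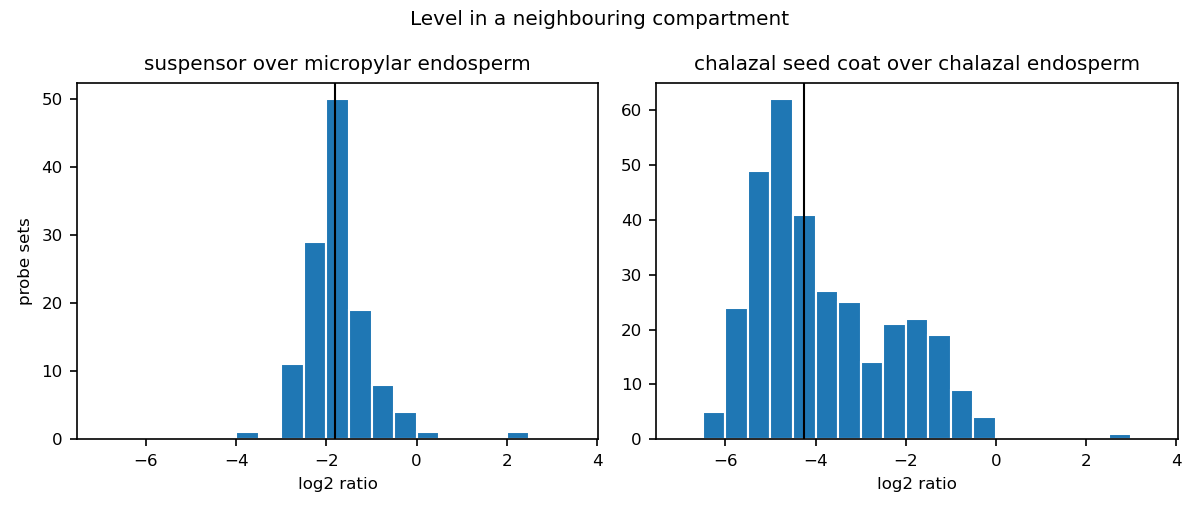
Histograms of the log2 ratio (x axis) of suspensor over micropylar endosperm for 124 bright micropylar genes and of chalazal seed coat over chalazal endosperm for 323 bright chalazal endosperm genes, with the number of probe sets on the y axis and a black line at each median. The medians lie at -1.80 and -4.26, and the second distribution has a long tail to the right.

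Both embryo parts together were set against the 3 endosperm parts. AT2G34700 stood at 13482 ± 8735 in embryo proper and 12179.9 ± 1977 in suspensor (SD, n = 2; at least 102-fold above endosperm, 3 of 7 endosperm arrays above background, adjusted p = 6.3e-12). LCR68, of a defensin-like family, stood at 2050.1 ± 722 and 32146 ± 223 (at least 47.9-fold), and ATLP-1, a thaumatin-like gene, at 9223 ± 4236 and 9899 ± 3403 (at least 63.0-fold, 5 of 7 endosperm arrays above background). Higher in endosperm were BGLU44, a beta-glucosidase, at least 29.8-fold with 2 of 4 embryo arrays above background, and the carboxypeptidase-like genes scpl21 (at least 24.5-fold) and scpl47 (at least 17.1-fold).

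All 10 photosynthesis genes were lower in embryo than in the mean of the 3 endosperm parts (10 adjusted over the list alone, median -1.99, camera adjusted p = 3.2e-10). Chalazal endosperm did not always follow that mean. PSAN stood at 199 ± 42.3 there, against 454 ± 134 in embryo proper and 495 ± 46.2 in suspensor. PRK stood at 12446 ± 5418 there, against 736 ± 211 and 710 ± 240. Type I MADS-box genes had 6 of 10 lower, none higher and 4 not called (7 lower adjusted over the list alone; median -2.82, adjusted p = 2.8e-06). Of 4 endosperm markers, 3 were lower in embryo, none higher and 1, IKU2, not called (3 adjusted over the list alone; median -3.58, adjusted p = 2.7e-04); AGL40 and AGL62 stand in both lists. Of 4 embryo proper markers, 3 were higher in embryo, none lower and 1, YAB3, not called (3 adjusted over the list alone; median 2.53, adjusted p = 0.00250). BBM, a transcription factor of embryo identity, stood at 695 ± 32.9 in embryo proper and 558 ± 172 in suspensor, and ACR4, a receptor kinase of the epidermis, at 2910.1 ± 1162 and 759 ± 375. ACR4 also stood at 1876 ± 1012 in general seed coat. Between embryo proper and suspensor, none of the 4 markers was called (camera adjusted p = 0.171). Between embryo and seed coat, 2 were higher in embryo and 2 not called (camera adjusted p = 0.106). In all, 3519 probe sets were higher and 2495 lower in embryo, 58.5% higher, and 44.2% of calls were higher when arrays were shifted to 1 common 75th percentile. A fit of these arrays alone, with the 2 regions as groups, called 1269.

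The embryo was also compared with the seed coat. AT3G24250 stood at 17596 ± 688 in embryo proper and 30554 ± 3182 in suspensor, at least 251-fold above seed coat with 1 of 4 seed coat arrays above background (SD, n = 2; adjusted p = 1.4e-11), and AT2G34700 was at least 131-fold above it. DFR, an enzyme of flavonoid synthesis, stood at 31040.3 ± 108 in general and 18846 ± 2003 in chalazal seed coat, at least 83.5-fold above embryo with 2 of 4 embryo arrays above background, and bZIP44, a transcription factor, at 7633 ± 661 and 22179 ± 3533 (at least 64.8-fold, 3 of 4 arrays). TBL38 was at least 78.0-fold and GILT, a thiol reductase, at least 78.8-fold above embryo, the latter with 2 of 4 arrays above background.

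Of 3 cell cycle genes, 2 were higher in embryo and 1 not called (2 adjusted over the list alone; median 2.39, adjusted p = 0.0170), which became adjusted p = 0.0838 with an estimated correlation. Of 10 photosynthesis genes, 5 were higher, 2 lower and 3 not called (7 higher and 2 lower adjusted over the list alone; median 0.77, adjusted p = 0.0305), against adjusted p = 0.268 with an estimated correlation. That list passed no longer without embryo proper 1 (0.0553), suspensor 1 (0.0543), chalazal seed coat 2 (0.0729) or general seed coat 2 (0.0712), nor with a larger offset (0.0782), a filter on dim probe sets (0.0544) or the compared arrays alone (0.0745). In all, 2304 probe sets were higher and 3092 lower in embryo, 42.7% higher, against 53.1% with a common 75th percentile. A fit of these arrays alone, with the 2 regions as groups, called 2109 in place of 5396.

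The endosperm was compared with the seed coat, and photosynthesis genes were higher in endosperm for 10 of 10 (10 adjusted over the list alone; median 2.98, adjusted p = 1.1e-11). PSAE-1, a subunit of photosystem I, stood at 7112 ± 452 in micropylar, 12889.5 ± 562 in peripheral (SD, n = 2) and 1579 ± 772 in chalazal endosperm (SD, n = 3), against 72.0 ± 16.9 in chalazal and 318 ± 211 in general seed coat. Chalazal endosperm was not higher for every gene. SBPASE stood at 706 ± 183 there, against 1004 ± 28.1 in chalazal and 1892 ± 251 in general seed coat. SWEET8, a sugar transporter first described in anthers, was 57.4-fold higher in endosperm (adjusted p = 1.4e-13), TBL42 was at least 57.8-fold and LCR24, a defensin-like gene, at least 64.3-fold higher, with 1 of 4 and 2 of 4 seed coat arrays above background. Lower in endosperm were bZIP44 (at least 72.6-fold), TBL38 (at least 47.8-fold) and AT1G62480 (at least 117-fold), with 1 of 7, 2 of 7 and 5 of 7 endosperm arrays above background.

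Type I MADS-box genes had 5 of 10 higher in endosperm, none lower and 5 not called (5 adjusted over the list alone; median 1.27, adjusted p = 3.2e-04), and all 4 endosperm markers were higher (4 adjusted over the list alone; median 1.75, adjusted p = 0.00169). These are means over the endosperm parts, and single parts could lie below seed coat. IKU2 stood at 849 ± 182 in micropylar but 5.74 ± 1.76 in chalazal endosperm, against 36.9 ± 14.1 in general seed coat. AGL40 stood at 247 ± 2.67 in micropylar endosperm, against 867 ± 621 in chalazal seed coat. MPC stood at 191 ± 116 in chalazal endosperm, against 214 ± 15.7 in general seed coat. AGL62 lay above both seed coat parts in each endosperm part. In all, 2676 probe sets were higher and 4531 lower in endosperm. The higher share was 37.1%, but 48.2% after quantile normalization and 59.3% with a common 75th percentile, so which direction held more genes depended on the scaling. With the 2 regions as groups and their arrays alone, 2916 were called in place of 7207.

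**Figure D3:**
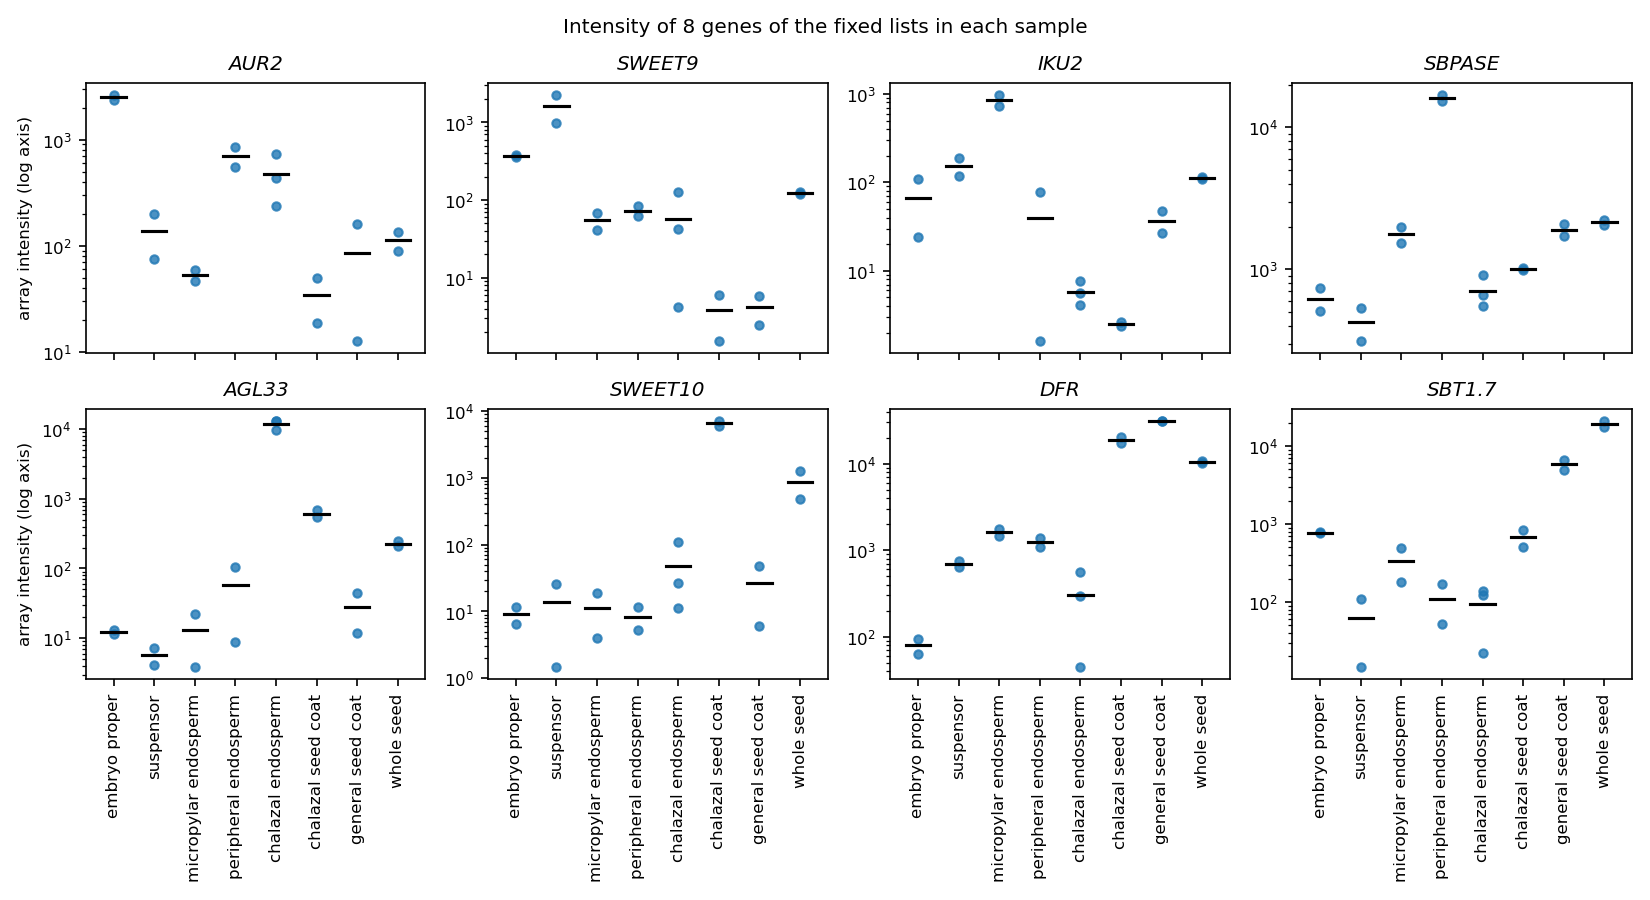
Array intensity (log axis) of 8 genes of the fixed lists, chosen after their values were seen, in each of the 8 groups, with points for samples and lines for means. AGL33 stands at 11862 in chalazal endosperm, SWEET10 at 6520.0 in chalazal seed coat and SBPASE at 16205 in peripheral endosperm.

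Genes highest in 1 compartment were called where a gene lay above each of the other 6 compartments. Chalazal endosperm had 614, among them AT3G60700 (86.9-fold above the next compartment, adjusted p = 4.0e-08), TET4, a tetraspanin (at least 60.3-fold), AT1G47810, AT2G44250 and SBT4.13. Chalazal seed coat had 226, among them SWEET10 (at least 53.2-fold), AT4G33550 (at least 177-fold), AT5G24580, AT4G22050 and AT5G40960. The count was 143 and 118 without chalazal seed coat 1 and 2. General seed coat had 180, among them AT5G62210 (at least 39.8-fold, 1 of 2 arrays of the next compartment above background), AT5G49180, AT4G03930, AT1G49800 and THI2.1 (30.1-fold). The count was 86 and 77 without general seed coat 1 and 2, and 113 without chalazal seed coat 1. THI2.1 was not called without micropylar endosperm 2 (adjusted p = 0.0516).

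Suspensor had 97 such genes, among them AT1G33590 (at least 25.6-fold, 1 of 2 micropylar arrays above background), AT3G62320 (27.8-fold), AT3G54940, AT1G51850 and AT1G62290; the count was 60 without embryo proper 1, and 36 and 27 without suspensor 1 and 2. Peripheral endosperm had 67, led by AT3G24790 (33.6-fold), MPC (27.2-fold), AT3G50720, AT1G66630 and AT5G54350. That count was 31 and 5 without peripheral endosperm 1 and 2, 42 and 43 without micropylar endosperm 1 and 2, 42 without embryo proper 2, and 42 and 41 without general seed coat 1 and 2. AT3G24790 (adjusted p = 0.0660) and AT3G50720 (0.0591) were not called without peripheral endosperm 2, nor AT5G54350 (0.0870) without peripheral endosperm 1. Embryo proper had 63, led by AT3G15720 (at least 41.8-fold, 1 of 3 chalazal endosperm arrays above background), AT1G80450, AT5G50915, AT1G53860 and AT4G09940. That count was 20 and 5 without embryo proper 1 and 2, 34 and 30 without suspensor 1 and 2, 40 without peripheral endosperm 2, 39 and 40 without chalazal seed coat 1 and 2, and 37 without general seed coat 2. AT1G80450 (adjusted p = 0.0520) was not called without embryo proper 2. AT1G53860 was not called without embryo proper 2 (0.219), micropylar endosperm 2 (0.146), peripheral endosperm 1 (0.157) or chalazal seed coat 2 (0.0711), nor AT4G09940 without embryo proper 1 (0.0680) or 2 (0.157), suspensor 2 (0.0887) or peripheral endosperm 1 (0.201). Without an offset limma called 0 genes for embryo proper and 0 for suspensor, with 438 and 318 at an unadjusted p under 0.05, and 16, 371, 46 and 24 for peripheral endosperm, chalazal endosperm, chalazal seed coat and general seed coat. With the offset 4 times as large, the count rose by over 1.5 times in each of these compartments except chalazal endosperm.

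For micropylar endosperm limma called 0 genes, with 571 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0683. It called 1 without micropylar endosperm 2, 3 without peripheral endosperm 2, 49 with a common 75th percentile, 12 with a filter on dim probe sets, 3 without the intensity trend and 193 with the larger offset. EXPA21 and TBL15, bright there, were also at 26421 ± 4304 and 7014 ± 419 in suspensor.

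Whole seed was set against the mean of the 7 compartments, taken on the log2 scale with equal weights. ARA12, the SBT1.7 subtilase of seed coat mucilage, stood at 19315 ± 2194 in whole seed and 5793 ± 1169 in general seed coat (SD, n = 2; at least 50.1-fold above the geometric mean of the compartments, adjusted p = 4.5e-09), and PRXR1, a peroxidase, at 28713 ± 3110.4 and 11811 ± 2192 (at least 48.0-fold). AT5G62210 was at least 56.4-fold higher. They had 12 of 15, 11 of 15 and 5 of 15 compartment arrays above background. Lower in whole seed were AT3G44050 (67.8 ± 21.1 against 9623 ± 162 in embryo proper; at least 17.7-fold), CHR23, a chromatin remodelling gene (13.8-fold), TGH, which acts in RNA processing (at least 12.8-fold, 1 of 2 whole seed arrays above background), and AT1G15940 (10.7-fold). In all, 2059 probe sets were higher and 900 lower, 69.6% higher, against 56.0% with a common 75th percentile. An equal mixture of the compartments would itself lie at or above a mean of log2 values, most so for genes bright in 1 compartment. The excess of higher calls and the folds above therefore cannot show what whole seed detects beyond the compartments. The count of 2959 was 988 and 1242 without whole seed 1 and 2, and 4817 with array weights. Whole seed also had the lowest GAPDH ratio, 2.99 ± 0.145, and the part of RNA quality in this count was not tested.

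Genes highest in a compartment were also looked up in whole seed. Both whole seed arrays were at or below background for 41 of the 97 suspensor genes (42.3%), 21 of 63 embryo proper genes, 133 of 614 chalazal endosperm genes, 34 of 226 chalazal seed coat genes, 5 of 67 peripheral endosperm genes and 5 of 180 general seed coat genes. The median log2 difference of whole seed from the compartment was -4.32 for suspensor genes, -3.66 for embryo proper, -3.76 for chalazal endosperm, -2.88 for peripheral endosperm, -2.65 for chalazal seed coat and -0.78 for general seed coat. AT1G33590, at 4357 ± 213 in suspensor, stood at 53.2 ± 52.6 in whole seed. Against every compartment at once, 25 probe sets were called lower in whole seed and 2 higher, against 50 and 1 after quantile normalization and 33 and 1 with a common 75th percentile. Those 2, named after their values were seen, were AT5G63180, at 1017 ± 175 in whole seed (SD, n = 2; limma adjusted p = 0.00198), and OCT1 at 1088 ± 675, with limma adjusted p = 0.0212, but 0.106 and 0.0549 under those scalings.

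The chalazal pole is shared by endosperm and seed coat, so the chalazal differences of both tissues were compared. Of 2569 probe sets higher in chalazal than other endosperm and 783 higher in chalazal than general seed coat, 267 stood in both lists, where independent lists would share 88.4. Both were lower for 223 against 120.5 of independent lists. Opposite directions were found for 56 and 38 against 90.8 and 117. Chalazal endosperm tissue in the chalazal seed coat captures could add to the 267, and these counts cannot tell it from a shared pole. AT3G03410, at 104929 ± 8728 in chalazal endosperm, stood at 6462 ± 5681 in chalazal and 184 ± 16.1 in general seed coat. The difference between the chalazal steps, chalazal minus peripheral endosperm less chalazal minus general seed coat, was past the threshold for 3583 probe sets, positive for 1650 and negative for 1933. For photosynthesis genes it was negative for 4 of 10, positive for none and not called for 6 (5 adjusted over the list alone; median -1.65, adjusted p = 2.7e-04; adjusted p = 0.0547 with an estimated correlation). The count was 2181 without chalazal seed coat 2, 2341 without general seed coat 1 and 2240 without an offset.

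Lists with 1 or 2 measured genes were not tested as lists. INO, an ovule identity gene, stood at 706 ± 18.8 and APL3, a subunit of the enzyme that starts starch synthesis, at 1361 ± 604 in general seed coat, against 62.4 ± 13.0 and 335 ± 56.5 in chalazal seed coat (SD, n = 2). YUC11, an enzyme of auxin synthesis, stood at 715 ± 392 in micropylar endosperm and 281 ± 10.7 in suspensor, and YUC4 was at most 109.8 ± 27.3 in chalazal endosperm (SD, n = 3). SWEET11, listed with vascular genes and transporters, stood at 47.2 ± 57.5 in chalazal endosperm with 1 of 3 arrays above background, and HSP22, the stress gene measured, was above background on 0 of the 17 arrays. The cytokinin and pollen lists passed the test in no comparison. Of the pollen genes, VEX1 reached 313 ± 215 in suspensor, and ANX1, ANX2 and HTR10 had means of at most 119.7 ± 14.2, 73.3 ± 94.8 and 109 ± 147. Across 72 list tests, 18 passed with the preset correlation and 13 of these with an estimated correlation.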

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

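The tests on chalazal endosperm genes in chalazal seed coat were chosen after the result was seen.

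The difference between the chalazal steps of endosperm and seed coat was tested by an interaction and was past the threshold for 3583 probe sets. The difference is the step of endosperm, chalazal less peripheral, minus the step of seed coat, chalazal less general. Photosynthesis genes had a median of -1.65 (camera adjusted p = 2.7e-04; adjusted p = 0.0547 with an estimated correlation). The difference was positive for AT1G53400 (9.87), AT2G45840 (8.73), AT5G59845 (8.43), AT2G06480 (7.78), AT5G13200 (7.72), AT1G11590 (7.60), AT4G32870 (7.49) and AT1G49800 (7.36), all on the log2 scale. AT1G11590 and AT1G49800 stood at 10906 ± 3110.1 and 12099.7 ± 1611 in general seed coat, 25.6 ± 30.7 and 48.8 ± 38.0 in chalazal seed coat and 52.1 ± 49.2 and 108 ± 113 in peripheral endosperm (SD, n = 2), and 56.4 ± 70.6 and 96.5 ± 70.0 in chalazal endosperm (SD, n = 3). Among these parts they were high only in general seed coat, so their positive differences came from that part. The difference was negative for AT4G33550 (-8.58), AT2G46600 (-8.48), AT2G38800 (-8.14), AT4G22050 (-7.51), AT5G24580 (-7.30), AT1G74055 (-6.94), AT4G16447 (-6.67) and AT4G16790 (-6.53).

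Of 335 bright genes called higher in chalazal endosperm than in embryo and the other endosperm, 289 lay higher in chalazal than in general seed coat, with a median of 1.22, where neither seed coat part had been used to choose them. This argues against signal of bright probe sets on every array as the source. Chalazal endosperm tissue in the seed coat captures, as the whole source, would give all genes 1 ratio, but of 323 bright genes called above every compartment except chalazal seed coat, 21.4% lay over 4-fold from the median ratio of 5.21%, 68 above and 1 below. For the other 254 genes, tissue of the neighbour and expression of the seed coat's own cannot be told apart, because they were picked by their ratio. For the 68 genes above the ratio, no biological explanation was tested. The count below the ratio is limited, because levels under an array's background limit were set to that limit.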

How the results depend on the processing

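The fits of only probe sets that name 1 gene, with the hybridisation covariate, without the 2 arrays of highest control signal (micropylar endosperm 1 and chalazal endosperm 2), with intensities scaled to a common 75th percentile before the offset, and with 4 regions as groups over all arrays were chosen after seeing the data. Of 174 named results, none turned direction under any setting run for it, where the fits with regions as groups covered 48. Quantile normalization and the common 75th percentile ended no call. Of the 30 genes highest in a compartment, 17 lost the call without an offset. No list turned direction. Among lists not called, photosynthesis genes in whole seed passed after quantile normalization (median 0.90, adjusted p = 0.00426), without an offset (0.0328), without general seed coat 1 (0.0458) and with only probe sets that name 1 gene (0.0405), over a range of 0.00426 to 0.172. Transporters in the difference of chalazal steps passed with the replicate block (0.0283), without chalazal endosperm 3 (0.0280) and without general seed coat 1 (0.0384; range 0.0280 to 0.194). Endosperm markers in micropylar with peripheral endosperm passed with only the groups compared (0.0463; to 0.219), and type I MADS-box genes in chalazal with general seed coat without chalazal seed coat 2 (0.0290; to 0.845). With the covariate, and without those 2 arrays, no count moved by over 1.5 times. For genes near the background limit, the size of the log2 difference depends on the offset. The cause of the moves below was not tested, except that fewer probe sets or fewer arrays enter some fits.

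With only probe sets that name 1 gene, counts were 1514 for embryo proper with suspensor, 3245 for chalazal with other endosperm, 1549 for micropylar with peripheral endosperm, 787 for chalazal with general seed coat, 3217, 2870 and 3923 for embryo with endosperm, embryo with seed coat and endosperm with seed coat, 1490 for whole seed and 1876 for the difference of the chalazal steps. Genes highest in embryo proper, suspensor, peripheral endosperm, chalazal endosperm, chalazal seed coat and general seed coat were 26, 43, 26, 362, 145 and 73. With only the groups compared, micropylar with peripheral endosperm gave 1480. Without an offset, chalazal with general seed coat gave 835 and the difference of chalazal steps 2240, and highest genes in embryo proper, suspensor, peripheral endosperm, chalazal endosperm, chalazal seed coat and general seed coat were 0, 0, 16, 371, 46 and 24; limma had 438 and 318 at an unadjusted p under 0.05 for the first pair. With the offset 4 times as large, highest genes in embryo proper, suspensor, micropylar endosperm, peripheral endosperm, chalazal seed coat and general seed coat were 180, 227, 193, 231, 399 and 380. Array weights gave 2606 for chalazal with general seed coat and 4817 for whole seed. With the 2 regions as groups in a fit of their arrays alone, embryo with endosperm gave 1269, embryo with seed coat 2109 and endosperm with seed coat 2916; with 4 regions as groups over all arrays these were 2144, 1623 and 3579. For genes highest in micropylar endosperm, a common 75th percentile gave 49, its form on intensities 18, the filter 12 and no intensity trend 3; without the trend, peripheral endosperm had 41. Fry called 35 of 72 lists, where camera called 18.

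Leaving out 1 array at a time, with the lone sample of a pair assumed to vary like the other groups, counts ran from 1578 to 3224 for embryo proper with suspensor, 5252 to 5921 for chalazal with other endosperm, 1807 to 3368 for micropylar with peripheral endosperm, 787 to 1739 for chalazal with general seed coat, 4554 to 6162 for embryo with endosperm, 4267 to 5756 for embryo with seed coat, 5865 to 7366 for endosperm with seed coat, 988 to 3190 for whole seed and 2181 to 3840 for the difference of chalazal steps. Highest genes ran from 5 to 78 in embryo proper, 27 to 108 in suspensor, 0 to 3 in micropylar endosperm (limma, with 449 to 589 at an unadjusted p under 0.05 where it was 0), 5 to 100 in peripheral endosperm, 493 to 596 in chalazal endosperm, 118 to 230 in chalazal seed coat and 77 to 191 in general seed coat, and called lists from 17 to 19.

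Replicate numbers did not pair the samples: same-numbered samples had a mean correlation of deviations of -0.00187 over 56 pairs, from -0.0933 to 0.0920. With the number as a replicate block, counts were 3045, 5584, 3090, 1625, 6051, 5489, 7272, 2981 and 3501 in the order above, highest genes 74, 97, 0 (566 at an unadjusted p under 0.05 in limma), 67, 556, 224 and 170, and called lists 19. Scaling moved the median log2 difference of all probe sets by over 0.1 in some comparisons: with quantile normalization embryo with seed coat went from -0.10 to 0.04, endosperm with seed coat from -0.06 to 0.14 and whole seed from 0.09 to -0.12. With a common 75th percentile embryo proper with suspensor went from 0.02 to 0.17, chalazal endosperm from 0.00 to 0.22, embryo with endosperm from -0.03 to -0.25, embryo with seed coat from -0.10 to 0.06, endosperm with seed coat from -0.06 to 0.32, whole seed from 0.09 to -0.11 and the difference of chalazal steps from 0.12 to 0.33. These 7 moved the same way, and less, when intensities were scaled.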

Other observations

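The gene families, grouped by shared symbols with at least 6 measured genes, the tests on micropylar genes in suspensor, the test on hybridisation controls and the splits by whole compartments were chosen after the result was seen; the other tests were not. Of 69 plastid genome genes, 64 were higher in endosperm than seed coat, 55 lower in embryo than endosperm, 39 lower in micropylar than peripheral endosperm, 21 lower and 3 higher in chalazal than other endosperm, and 3 lower in chalazal than general seed coat. The medians were 1.47, -1.55, -1.15, -0.49 and -0.72, which kept their sign under each scaling, beside 2.98, -1.99, -1.76, -1.90 and -1.07 for photosynthesis genes, and the groups were not tested against each other. The plastid test gave adjusted p = 7.3e-33, 2.7e-31, 2.6e-22, 0.0161 and 1.7e-09, but adjusted p = 0.192, 0.192, 0.233, 0.687 and 0.426 with an estimated correlation. In whole seed 6 were higher and 12 lower, with a median of -0.14, and 0.01 after quantile normalization (adjusted p = 0.0205; adjusted p = 0.691 with an estimated correlation), beside 0.66 for photosynthesis genes, whose test was not passed.

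IQD genes, of a calmodulin-binding family, had 10 of 15 higher in embryo than endosperm, none lower (median 1.80; adjusted p = 1.1e-05, and adjusted p = 0.148 with an estimated correlation). ATG genes, of autophagy, had 4 of 8 lower in embryo proper than suspensor (median -1.94; adjusted p = 1.8e-05, and adjusted p = 0.233 with an estimated correlation) and 5 of 8 higher in chalazal than other endosperm (median 1.12; adjusted p = 0.0306, and adjusted p = 0.426 with an estimated correlation). LCR genes, of a defensin-like family, had 4 of 9 lower in embryo proper than suspensor (median -2.57; adjusted p = 0.0104, and adjusted p = 0.254 with an estimated correlation). Median log2 levels of LCR and ATG genes were 8.91 and 10.66 in suspensor and 9.42 and 10.13 in micropylar endosperm, and LCR24 is one of the 124 bright micropylar genes that were also high in suspensor. Over 342 family tests, 21 passed with limma's camera at the preset correlation and 0 with an estimated correlation, which adjusts for genes that vary together.

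Genes called higher in micropylar endosperm than in the other endosperm and seed coat parts were also high in suspensor, at a median 28.6% of the micropylar level over 124 bright genes. Signal of bright probe sets on every array is excluded, since suspensor lay above embryo proper, which had no part in choosing the genes, by a median of 2.90, in 124 of 124. Only 0.806% of the genes lay over 4-fold from the median ratio, a ratio that tissue of micropylar endosperm in the suspensor captures would give. That tissue may be the source, and suspensor expression of its own stays open. As values without a verdict, the same ratio was 3.47% for micropylar genes in embryo proper, 8.61% for suspensor genes in micropylar endosperm, 23.1% for embryo proper genes in suspensor and 9.23% for peripheral endosperm genes in general seed coat. In that order, 10.5%, 47.2%, 40.8% and 4.76% of the genes lay over 4-fold from the median ratio. The medians for suspensor and embryo proper genes thus describe no common ratio.

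Whole seed was called below every compartment for 25 probe sets, by a median of 2.13 below the lowest (quartiles 1.78 and 2.45), which a mixture of the 7 compartments on a common scale would not give. Spiked hybridisation controls, which follow the scale of an array, lay at -0.0300 from the compartment mean in whole seed (SD of the compartment arrays 0.53), so a scale of whole seed lower by that gap is excluded. With all arrays set to equal controls the quartiles of the gap were 1.57 and 2.37 and all 25 lay below every compartment mean, but only 3 were called, as the median SD of these probe sets went from 0.38 to 0.62. Quantile normalization called 25 of the 25 and a common 75th percentile 24, but both lower whole seed, from a median of 0.09 over all probe sets to -0.12 and -0.11, and so decide nothing here. Tissue outside the captured compartments and the different handling of whole seeds were not tested.

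Other splits were counted with only the compared arrays and 1 mean per side, so the real splits call fewer than the fit of all 17 arrays. For chalazal with other endosperm, 1 of 35 splits, the real one, gave as many as its 2570 calls, and the highest other gave 1. For embryo with seed coat it was 1 of 35, with 2109 against 25, and for endosperm with seed coat 1 of 100, with 2916 against 687. For embryo with endosperm 2 of 100 splits gave as many as 1269. The other, with the 3 chalazal endosperm arrays and micropylar endosperm 1 on 1 side, called 2212, which points to a structure of the samples beyond the compared groups. Hybridisation controls on these arrays lay at 15.75, 16.28, 15.25 and 15.9 on the log2 scale. They were at most 15.15 on the other embryo and endosperm arrays. Whether array quality or tissue made this split was not tested. Splits of single arrays part the arrays of a compartment, which are alike, so few calls in them say little about chance between compartments. Whole compartments were therefore also moved between the sides. Their 3 splits for chalazal with other endosperm, 10 for embryo with endosperm, 3 for embryo with seed coat and 10 for endosperm with seed coat are too few for a share under 0.05. The highest other split gave 371 against 2570, 2142 against 1269, 25 against 2109 and 1590.0 against 2916.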
